A study of Mus musculus with 3 samples.

How the data were processed

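The series holds 3 single-cell RNA libraries of viable CD45-positive, DAPI-negative cells sorted from 2208L mammary tumours of mice, all with the same labels. The sample labels name the cell type as tumour although the cells were sorted for CD45, and they name both a 5′ platform and a 3′ protocol, which was not settled. Per the submitters' processing notes, Cell Ranger, Seurat and the mm10 build were used; their versions are not given in the sources used here. The matrix headers state a software version of 3.0.0 without naming the software. The deposited matrices hold UMI counts per gene and barcode (28692 genes), as whole numbers and unnormalised, with at least 500 UMIs in every barcode. The comparisons, the gene lists, the marker sets, the tests and most alternatives were fixed before the data were examined.

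Barcodes with under 200 genes (22) or over 10% mitochondrial UMIs (107) were left out, which kept 14226 of 14336. Scrublet scores were computed per library, but the caller marked 2 barcodes (0.0141%) and so has not worked; these 2 were left out, and an alternative leaves out the 560 barcodes with the highest scores at a rate of 0.8% per 1000 barcodes. Counts were scaled to 10000 per barcode and log-transformed, 2000 variable genes were chosen, Icam1 and the adhesion genes were taken out of them, and 30 principal components, 15 neighbours and Leiden clustering at resolution 1 were used (scanpy 1.11.5, igraph 0.11.9, anndata 0.12.19, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, Python 3.11.15). No batch correction was applied. A cluster was named after a marker set when at least 3 of its markers were present in 10% of its barcodes and 2-fold above the other clusters with 10 CPM added, and the set with the highest mean fold was taken. A cluster of 261 barcodes with T-cell and neutrophil transcripts and a median doublet score above 0.15 was left unnamed and used in no comparison. Classes with under 20 barcodes in a library were not tested, which left out the B-or-plasma-cell-like class (19, 37 and 13 barcodes).

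UMIs were summed per library and class, or per library and Icam1 status, so cells are not treated as replicates. The sums were tested with edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) with TMM scaling, filterByExpr, library as a block and the Benjamini-Hochberg adjustment at 0.05. Both sums of a pair come from the same library, which is where the pairing comes from. The neutrophil-like sums were compared with those of each other class in a joint fit. For the Icam1 split each barcode was thinned at random to 600 UMIs (the 25th percentile of neutrophil-like totals, rounded down), and 770 shallower neutrophil-like barcodes were left out; the thinned shares by class came from a separate draw. Detected means at least 1 Icam1 UMI after thinning; an alternative set at least 2 before thinning against 0. Icam1 itself is not counted among the calls. An alternative drew 3278 undetected neutrophil-like barcodes to the subcluster mix of the detected ones in each library, at the highest ratio that every subcluster allowed. The difference between classes used library within class as a block. Its scaling deviates from the plan, which assumed TMM: with TMM the simulated values were biased and the median of all genes lay at 0.44 (log2), so library totals were used and TMM was kept as an alternative. Neutrophil-like barcodes were sub-clustered at resolution 0.5, and each subcluster was tested against the mean of the others. Adjusted p for Icam1 in the subclusters was taken over the subclusters, not over all genes. Standard errors come from the F statistic of the test, and log2 values per library carry a prior count of 0.5.

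Of 16 gene lists (208 genes) and 16 marker sets (141 genes), 15 lists and 3 marker sets had the minimum of 3 measured members and were tested with camera at a preset correlation of 0.01, with the adjustment over the lists; camera with an estimated correlation and fry were run beside it. The list of primary granule and proliferation genes had too few measured members for a test. Acod1 and Jaml were matched by identifier as Irg1 and Amica1, and Itgam by its Ensembl identifier since its symbol occurs on more than 1 gene. The genes named are the 10 highest and 10 lowest fold changes in the neutrophil-like split (5 and 5 in the other contrasts) with an adjusted p under 0.05, a mean log2 level of at least 5 and the same direction in every library, without predicted, ribosomal or mitochondrial genes. To these were added up to 4 called members of each list, or the 2 with the lowest p where none was called. In the class contrast they are Icam1, Itgb2, Itgal, Itgam, Itgax and the 4 adhesion genes with the largest difference. Some genes that these rules name are not reported here. Il1b, Saa3 in the difference between classes, and the genes of other cell classes listed as levels were named after their values were seen. Positions are 1-based, from GENCODE M21 on GRCm38, the assembly also called mm10, for 54 of 54 named genes; the annotation release used for the counts is not given in the sources used here.

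The fits were tested on simulated data with 200 changed genes. For the neutrophil-like split 7.5% of genes changed 1.5-fold, 41.8% changed 2-fold and 66.7% changed 4-fold were recovered, with 2 false calls. The monocyte/macrophage-like split recovered 7.5%, 19.4% and 51.5% with 1 false call, the class contrast 25.4%, 74.6% and 89.4% with 6, the difference between classes 3.0%, 4.5% and 30.3% with 0 false calls, and subcluster 3 against the others 67.2%, 86.6% and 89.4% with 6. A list raised 1.5-fold in simulation had an adjusted p of 3.47e-39 with the preset correlation and 0.222 with an estimated correlation, which missed it, and 0 of 15 lists without a raised gene were called by camera. Genes were drawn independently there, so the simulation cannot test the preset correlation for lists whose members move together. In the neutrophil-like split the estimated correlation was 0.157 for the NF-kB list and 0.326 for the interferon list, and ran from -0.178 to 0.644 over the lists. Alternatives covered the barcode filter, clustering resolution, doublets, thinning depth, draw and threshold, 7 marker genes of other cells, the mix of subclusters, scaling, the gene filter, the block, DESeq2 1.42.0 in place of edgeR, and each library left out. Shares of single libraries carry exact Clopper-Pearson intervals. Alignment and raw reads were not analysed here.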

Results

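Single-cell RNA was measured in 3 libraries of 1 group. They came from mouse mammary tumours grown for 4 weeks from injected 2208L tumour cells to a diameter of 0.7 to 1 cm, from which viable CD45-positive cells had been sorted as DAPI-negative. The total depth was 9846404 UMIs (unique molecular identifiers, each counting 1 captured transcript) in replicate 1, 15259236 in replicate 2 and 9445914 in replicate 3, over 4424, 6036 and 3876 barcodes. After filtering, 4380, 6007 and 3839 barcodes remained, with medians of 1239, 1549 and 1318 UMIs. Nothing in the labels says that the 3 libraries are separate animals, so every p-value speaks only for these samples. With library as a block, the tests weigh a difference within libraries against how much it varies between them. The series title names ICAM1-high neutrophils. Each comparison was therefore made within the libraries, between classes of barcodes, and transcript detection is not surface protein.

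The first question was which cells the sorted fraction held. Neutrophil-like barcodes, which express the calprotectin genes S100a8 and S100a9, were the most frequent class at 45.0% ± 13.3 (SD, n = 3). T-cell-like barcodes made up 21.7% ± 3.88, and monocyte-like and macrophage-like barcodes together 20.8% ± 6.24, of which 17.2% ± 4.85 were macrophage-like and 3.61% ± 1.69 monocyte-like. At Leiden resolution 0.5, 0 barcodes were named monocyte-like and 20.8% ± 6.26 macrophage-like, so this division depended on the resolution. Dendritic-cell-like barcodes reached 4.18% ± 1.37, NK-cell-like 2.98% ± 1.42 and plasmacytoid-dendritic-cell-like 1.24% ± 1.01. Epithelial-like barcodes, which express Epcam and keratins and should have been removed by the CD45 sort, were 1.87% ± 0.272, and B-or-plasma-cell-like barcodes 0.463% ± 0.141. The neutrophil-like share was 38.9% in replicate 1 (95% Clopper-Pearson interval 37.5 to 40.4), 35.8% in replicate 2 (34.6 to 37.0) and 60.3% in replicate 3 (58.7 to 61.8). These intervals do not overlap between replicate 3 and the other libraries, and they cover counting error only. With at least 500 genes and at most 5% mitochondrial UMIs per barcode the neutrophil-like share was 28.6% ± 17.3 and the monocyte/macrophage-like share was 29.1% ± 9.81, so the order of these classes depended on the filter.

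**Figure D1:**
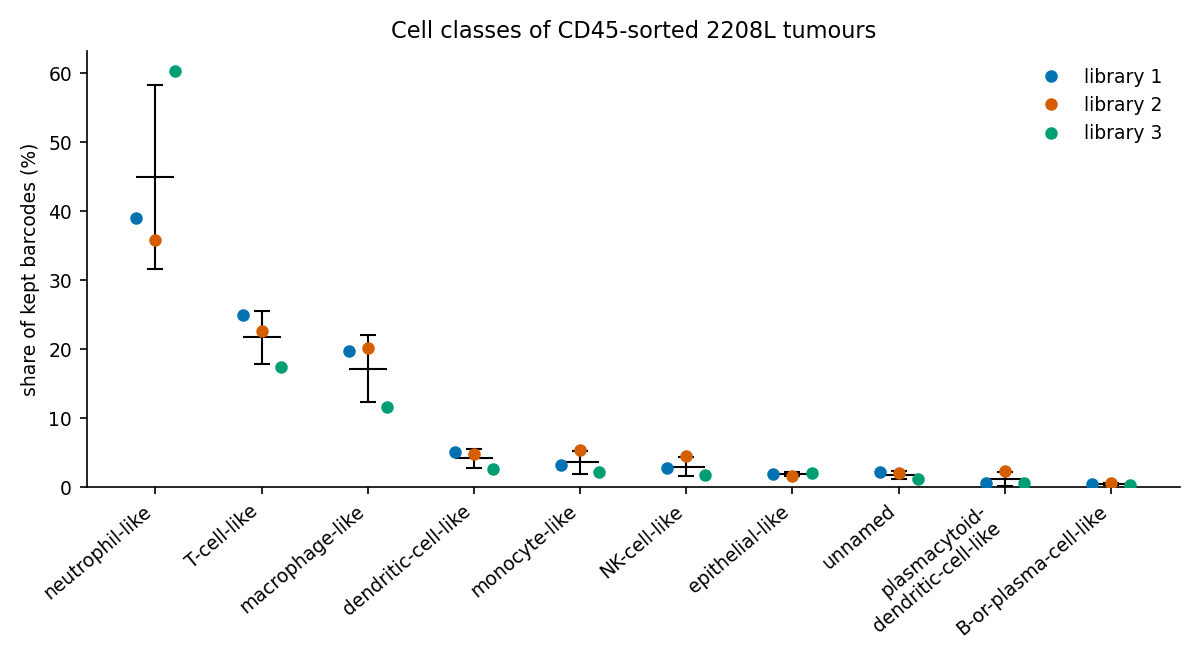
Share of kept barcodes in each cell class (vertical axis, percent) for the 3 libraries (points), with the mean and SD (black). Neutrophil-like barcodes range from 35.8% to 60.3% of a library.

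The second question was where Icam1 was transcribed. Icam1 (ENSMUSG00000037405; GRCm38 chromosome 9, 21015985 to 21028817) encodes an adhesion molecule bound by the leukocyte integrins. Its level was highest in neutrophil-like barcodes, at 136 ± 12 CPM (UMIs of the gene scaled by the summed UMIs of the class in a library; SD, n = 3; 867 Icam1 UMIs). It was 52.5 ± 3.69 in monocyte/macrophage-like, 39.7 ± 7.72 in dendritic-cell-like, 29.6 ± 16.7 in NK-cell-like, 24.7 ± 3.70 in T-cell-like and 23.5 ± 13.2 in plasmacytoid-dendritic-cell-like barcodes. Epithelial-like barcodes had the lowest level of the classes tested, 5.23 ± 4.09, from 14 Icam1 UMIs. In edgeR's quasi-likelihood test over 9451 genes the neutrophil-like level lay above the monocyte/macrophage-like level by 1.63 ± 0.14 (log2, standard error; adjusted p = 6.65e-13), and it was higher in 3 of 3 libraries. The difference was 1.93 against dendritic-cell-like (adjusted p = 6.65e-12), 2.69 against plasmacytoid-dendritic-cell-like (adjusted p = 5.32e-10), 2.65 against T-cell-like (adjusted p = 2.78e-16), 2.57 against NK-cell-like (adjusted p = 3.31e-10) and 4.99 against epithelial-like barcodes (adjusted p = 1.1e-18), each higher in 3 of 3 libraries. The median of all genes in the monocyte/macrophage contrast moved from -0.10 with TMM to -0.35 with library totals, and Icam1 lay 1.73 above that median with either scaling.

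**Figure D2:**
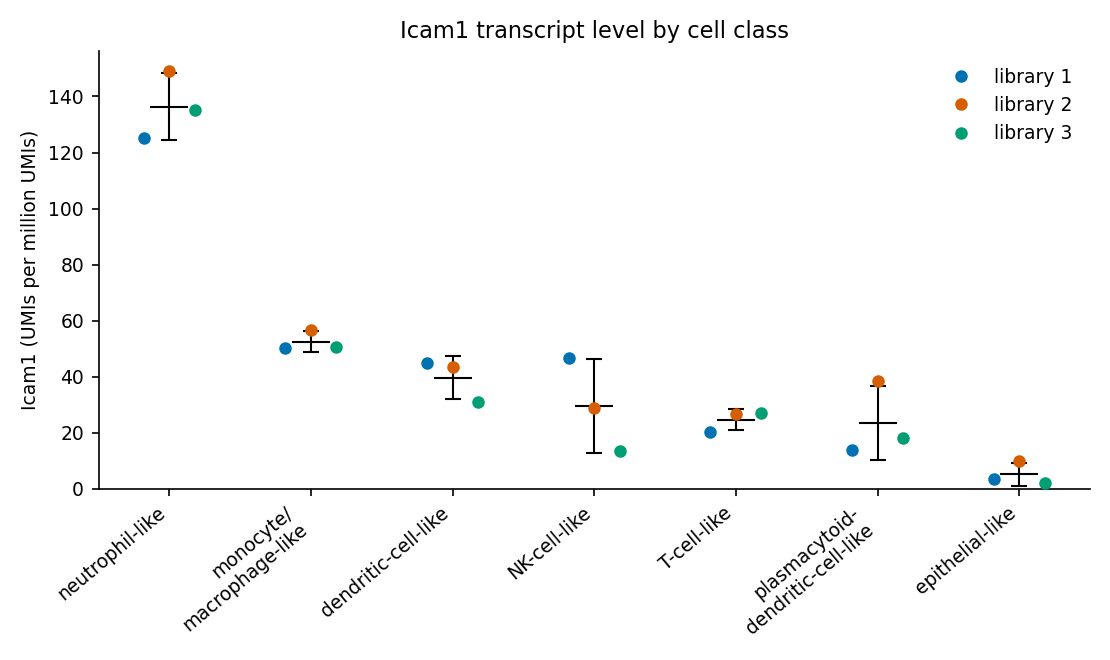
Icam1 level in CPM (vertical axis) by cell class for the 3 libraries (points), with the mean and SD (black). The neutrophil-like sums lie between 125 and 149, above every other class in all 3 libraries.

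The share of barcodes with an Icam1 UMI ran the other way without thinning, as the classes differed in UMIs per barcode. In all, 867 Icam1 UMIs fell in 6167 neutrophil-like and 807 in 3075 monocyte/macrophage-like barcodes. Per barcode the count was thus higher in monocyte/macrophage-like barcodes, and the CPM ranking holds only as a share of all UMIs. Whether the depths differ by RNA content per cell or by capture was not tested. Without thinning it was 11.2% ± 1.17 in neutrophil-like barcodes (median depth 901 UMIs) and 21.5% ± 3.39 in monocyte/macrophage-like barcodes (median 4282 UMIs). With every barcode thinned to 600 UMIs it was 7.11% ± 0.211 and 3.15% ± 0.420. Epithelial-like barcodes, the tested class with the lowest Icam1 CPM, had 3.38% ± 1.68 without thinning at a median depth of 9137.5 UMIs and 0.370% ± 0.642 after it. Of the neutrophil-like barcodes, 5470 held no Icam1 UMI, 573 held 1, 93 held 2 and 31 held 3 or more, so most detected barcodes lay at the threshold, and a separate high group cannot be told apart at this depth. After thinning 339 of 385 detected barcodes held 1 Icam1 UMI.

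The chains of LFA-1 and Mac-1, integrins that bind ICAM1, were not called different between neutrophil-like and monocyte/macrophage-like barcodes by this test. The log2 difference was 0.07 ± 0.13 for Itgb2, the shared beta chain (adjusted p = 0.622), 0.02 ± 0.16 for Itgal, the alpha chain of LFA-1 (adjusted p = 0.909), and -0.06 ± 0.16 for Itgam, the alpha chain of Mac-1 (adjusted p = 0.734). In CPM all of these were lower in neutrophil-like barcodes in 3 of 3 libraries, and with library totals the Itgb2 and Itgal differences turned to -0.18 and -0.23. Itgax, the alpha chain of p150,95, was lower by a log2 difference of -0.73 ± 0.14 (adjusted p = 2.88e-05). In CPM it lay lower than in the pooled class and than in macrophage-like barcodes in 3 of 3 libraries. Against monocyte-like barcodes it lay higher in 3 of 3 libraries, so the pooled difference does not hold for both parts of the class. The junction gene F11r was lower at -3.51 ± 0.26 (adjusted p = 2.35e-14), and so was Fermt3, which encodes the integrin activator kindlin-3, at -2.08 ± 0.16 (adjusted p = 4.01e-14), each in its direction in 3 of 3 libraries. Cd99l2 had 0 UMIs in the neutrophil-like and 80 in the monocyte/macrophage-like barcodes, at least 11.2-fold lower with a floor of 3 counts over the class. Of the 21 measured genes of the adhesion list with Icam1, 6 were higher, 9 were lower and 6 did not pass, and 15 passed when adjusted over the list alone. Without replicate 1 or without replicate 3, 13 passed.

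The third question was what else differs in neutrophil-like barcodes with an Icam1 UMI, whether from the cell itself or from free RNA. After thinning to 600 UMIs, 385 barcodes had Icam1 (96, 130 and 159 by replicate) and 5012 did not. Saa3, an acute-phase gene (ENSMUSG00000040026; chromosome 7, 46711998 to 46715700), rose most among the named genes, by 1.73 ± 0.17 (log2, standard error; adjusted p = 1.7e-14), from 403 ± 183 to 1344 ± 905 CPM (SD, n = 3). The interferon-induced chemokine gene Cxcl10 (ENSMUSG00000034855; chromosome 5, 92346638 to 92348889) rose by 1.52 ± 0.17 (adjusted p = 1.94e-11). Dusp2, which encodes a phosphatase of MAP kinases, rose by 1.47 ± 0.18 (adjusted p = 4.08e-10), the fatty-acid receptor gene Gpr84 by 1.35 ± 0.22 (adjusted p = 8.74e-06), the cytokine gene Tnf by 1.24 ± 0.20 (adjusted p = 5.28e-06) and the mitochondrial superoxide dismutase gene Sod2 by 1.02 ± 0.18 (adjusted p = 5.3e-05). Ralgds, Nfkbie, Igtp and Ifi47 rose by 0.91 to 1.61 with adjusted p from 0.0334 to 0.0468. Retnlg (ENSMUSG00000022651; chromosome 16, 48872621 to 48874496), a resistin-like gene of circulating neutrophils, changed by -2.20 ± 0.28 (adjusted p = 2.53e-09), from 410 ± 137 to 86.1 ± 41.4 CPM. Prok2, which encodes a secreted peptide, changed by -1.64 ± 0.28 (adjusted p = 1.68e-05), the galectin gene Lgals3 by -0.88 ± 0.15 (adjusted p = 2.07e-05), S100a8 by -0.64 ± 0.09 (adjusted p = 1.28e-08) and S100a9 by -0.47 ± 0.08 (adjusted p = 4.76e-05). Gpi1, Wfdc17, Emilin2, S100a11 and S100a6 fell by 0.55 to 0.74, with adjusted p from 8.31e-07 to 0.0375. Each of these 20 genes had its direction in 3 of 3 libraries, as the rule for naming them required.

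**Figure D3:**
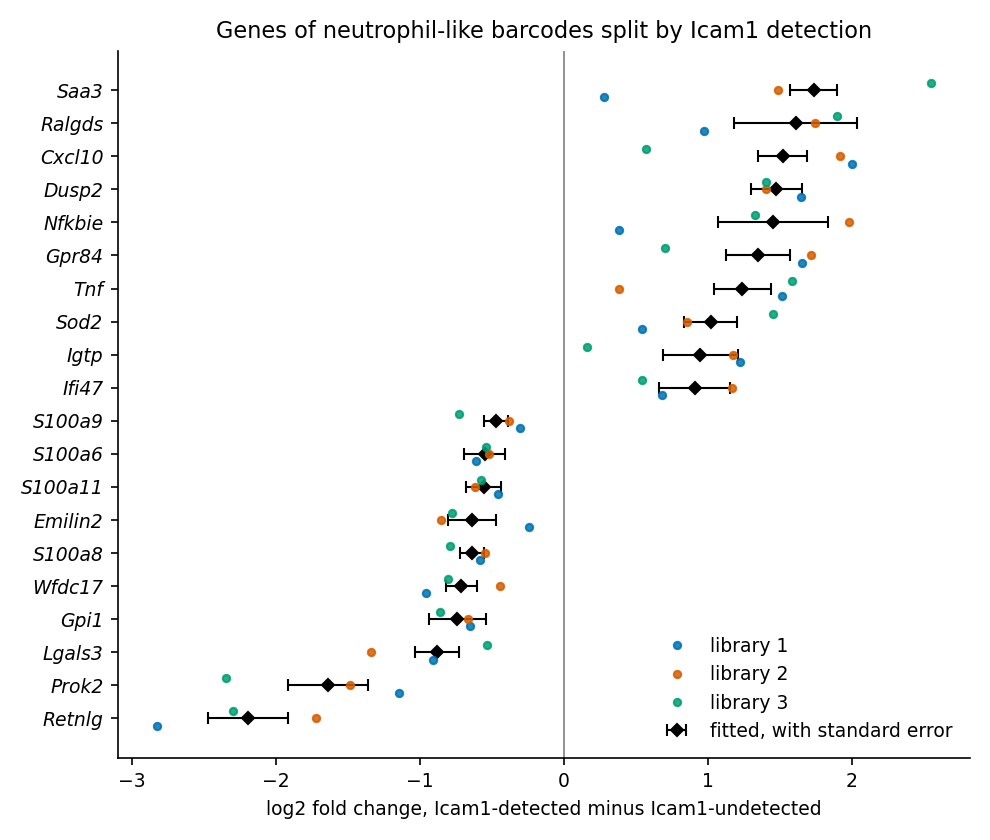
Log2 fold change between Icam1-detected and Icam1-undetected neutrophil-like barcodes (horizontal axis) for 20 named genes, per library (coloured points) and as fitted with its standard error (black). Saa3 has the highest fitted value (1.73) and Retnlg the lowest (-2.20).

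In all, 36 of 4042 genes passed edgeR's quasi-likelihood test, 24 higher and 12 lower, 345 had an unadjusted p under 0.05, and DESeq2 called 16, all of them among the 36. The balance of directions depended on the setting: thinned to the 50th percentile, 19 genes were higher and 35 lower among 54 calls, and without the filter on low counts 12 were higher and 60 lower among 72. The median depth before thinning was 901, 950.5 and 1046 UMIs in detected barcodes and 900.5, 874 and 1079 in undetected ones. The size of this list rested on replicate 3, without which 5 genes passed, while 17 passed without replicate 1 and 23 without replicate 2. Of 26 genes named from this split, Cxcl10, Dusp2 and Nfkbia passed with any library left out. Splits by 20 control genes of like detection gave 2 to 483 calls (median 77.5), and 12 of the 20 gave at least 36, so the number of calls alone does not set Icam1 apart. The highest log2 change in any control split was 0.27 for Tnf and 0.24 for Nfkbia, against 1.24 and 0.86 in the Icam1 split. The lowest was -0.81 for Tnf and -1.33 for Nfkbia, so control splits also moved Nfkbia by more than 0.86, but downwards. Both genes were named because the Icam1 split called them. Retnlg lay below its -2.20 in 6 of the 20, down to -3.48. Of the undetected barcodes, 253 (5.05%) had an Icam1 UMI before thinning, which draws the groups together.

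Targets of NF-kB and inflammatory cytokines were higher in Icam1-detected neutrophil-like barcodes. Of 19 measured genes 6 rose and 13 did not pass, and 12 rose and 1 fell when adjusted over the list alone. Besides Tnf and Sod2 these were the NF-kB inhibitor gene Nfkbia (0.86 ± 0.11, adjusted p = 9.48e-10), the chemerin receptor gene Ccrl2 (0.58 ± 0.10, adjusted p = 2.07e-05), the interleukin gene Il1b (0.36 ± 0.09, adjusted p = 0.0106) and the chemokine gene Ccl4 (0.41 ± 0.10, adjusted p = 0.0147, higher in 2 of 3 libraries). The list median was 0.58 and camera with a preset correlation gave an adjusted p = 4.24e-18, but an adjusted p = 0.279 with an estimated correlation. Interferon-stimulated genes had a median of 0.32 (adjusted p = 1.16e-09; adjusted p = 0.344 with an estimated correlation). Of 14 measured, 3 rose, namely Cxcl10, the GTPase gene Ifi47 and Ifit1 (0.57 ± 0.14, adjusted p = 0.0176), 11 did not pass, and 4 rose when adjusted over the list alone. Apart from Ccl4 these genes were higher in 3 of 3 libraries, and each list median was above 0 in 3 of 3 libraries.

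Blood neutrophil genes were lower, with a median of -0.34 (adjusted p = 6.68e-08; adjusted p = 0.279 with an estimated correlation). Of 10 measured genes 3 fell (Retnlg, S100a8 and S100a9), 7 did not pass, and 3 fell when adjusted over the list alone. The neutrophil markers, which hold 8 of the 11 members of that list, had a median of -0.15 (adjusted p = 4.53e-07; adjusted p = 0.344 with an estimated correlation), with 3 of 14 lower, 11 not passing and 5 lower when adjusted over the list alone. It was not called with at least 500 genes and at most 5% mitochondrial UMIs (adjusted p = 0.244) or with at least 2 Icam1 UMIs before thinning against 0, which leaves out barcodes with 1 (adjusted p = 0.0641), in a range of 2.61e-09 to 0.244 over 18 alternatives. Genes of hypoxia and glycolysis had a median of -0.28 (adjusted p = 7.56e-05; adjusted p = 0.279 with an estimated correlation), although 0 of 18 passed in edgeR (2 fell when adjusted over the list alone). The lowest p in that list were those of Bnip3 (-0.57, adjusted p = 0.091, lower in 3 of 3 libraries) and Hilpda (-0.38, adjusted p = 0.227, lower in 2 of 3 libraries). Granule proteins had a median of -0.45 (adjusted p = 0.0405; adjusted p = 0.542 with an estimated correlation), with 0 of 7 genes passing in edgeR and 2 falling when adjusted over the list alone; the lowest p were those of Wfdc21 (-0.45) and Lcn2 (-0.52). Without replicate 1 or 3 the granule list was not called (adjusted p = 0.316 and 0.377; 0.0011 to 0.829 over 18 alternatives, of which 8 called it). In subclusters 3 and 5 alone, the ones with at least 10 detected barcodes in each library, the blood neutrophil list was not called with subcluster in the block (median -0.14, adjusted p = 0.189) or without it (-0.23, adjusted p = 0.14; 1.03e-12 to 0.189 over 18 alternatives). Its called genes were not called there either: with subcluster in the block Retnlg was at -1.36 (adjusted p = 0.181; 3.61e-38 to 0.181 over the alternatives), S100a8 at -0.31 (adjusted p = 0.149; 1.1e-18 to 0.411) and S100a9 at -0.31 (adjusted p = 0.149; 3.15e-12 to 0.812), and without it at -1.40, -0.34 and -0.30. With undetected barcodes of all subclusters drawn to the subcluster mix of detected ones the blood neutrophil list was called (-0.24, adjusted p = 1.13e-05), and the hypoxia list was not (-0.09, adjusted p = 0.174, the highest of a range from 7.14e-14). Each of these 4 medians was below 0 in 3 of 3 libraries. In control splits the blood neutrophil list was called lower in 17 of 20, hypoxia and glycolysis in 13, the interferon list higher in 2 and the NF-kB list higher in 0. Over these splits the NF-kB median ran from -0.52 to 0.03. The interferon median ran from -1.17 to 0.51, and in the split by Max it lay above the 0.32 of the Icam1 split. The rise of the interferon list alone therefore does not set the Icam1 split apart. In most control splits the NF-kB list was lower at an unadjusted camera p under 0.05 with the preset correlation. This p was 4.13e-10 in the split by Ndufb3, 8.96e-10 in that by Snrpd3 and 4.81e-09 in that by Emg1. The control splits called 2 to 16 lists, against 6 in the Icam1 split, so the number of lists alone does not set Icam1 apart. With an estimated correlation 0 lists passed, 3 had an unadjusted p under 0.05, and fry, which asks whether a list's genes move on balance in a single direction, called 1 list (NADPH oxidase).

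**Figure D4:**
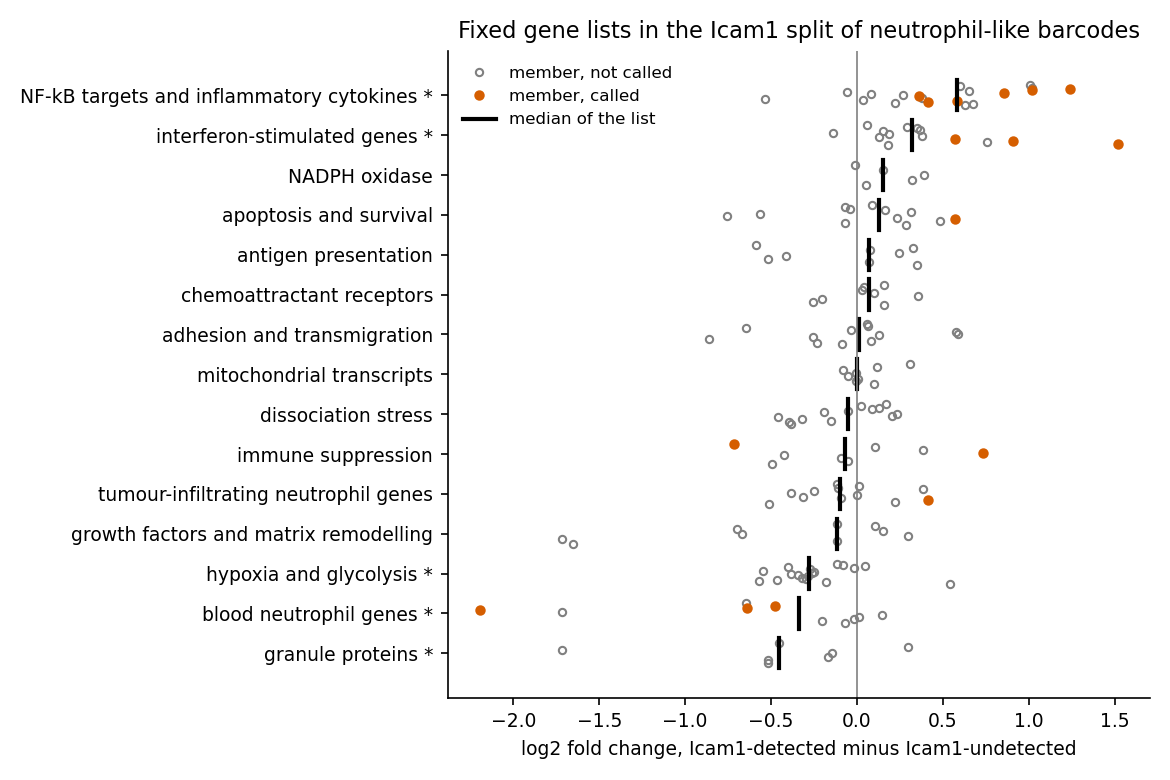
Log2 fold change between Icam1-detected and Icam1-undetected neutrophil-like barcodes (horizontal axis) for the measured members of 15 fixed gene lists (points, filled where called) with the list medians (black bars). Asterisks mark lists called by camera with a preset correlation, none of which passed with an estimated correlation.

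The adhesion and transmigration list was not called (adjusted p = 0.892). None of its 12 measured genes passed in edgeR, and 0 passed when adjusted over the list alone; its median was 0.01, its mean -0.05 and its test pointed up, while the median lay below 0 in 3 of 3 libraries. Itgb1, an integrin beta chain, had the lowest p (0.58 ± 0.35, adjusted p = 0.738, higher in 3 of 3 libraries). Chemoattractant receptors (8 measured, 0 passing, 0 over the list alone) had a median of 0.07 (adjusted p = 0.527), with Cxcr4 at 0.35 and Ccr1 at -0.26. Of 12 tumour-infiltrating neutrophil genes only Ccl4 rose, and 1 rose and 3 fell when adjusted over the list alone (median -0.10, adjusted p = 0.527). Immune suppression had Irg1, a gene of itaconate synthesis, higher (0.73 ± 0.15, adjusted p = 0.000735) and Wfdc17 lower among 8 (1 each when adjusted over the list alone; median -0.07, adjusted p = 0.527). Of 12 genes of apoptosis and survival Bcl2a1b rose (0.57 ± 0.13, adjusted p = 0.00845), with 2 over the list alone (median 0.13, adjusted p = 0.159), although near-identical copies make reads of the Bcl2a1 genes hard to assign. None of the genes passed in NADPH oxidase (5; median 0.15, adjusted p = 0.129; Ncf1 0.32), growth factors and matrix remodelling (9; -0.12, adjusted p = 0.0973; Osm -0.67, Plaur -0.70) or dissociation stress (13; -0.05, adjusted p = 0.373; Dusp1 -0.40, Fos -0.32). When adjusted over the list alone these gave 0, 3 lower and 2 lower. Antigen presentation (8 genes, 0 passing, 1 higher over the list alone) had a median of 0.07, a mean of -0.06 and a test pointing up (adjusted p = 0.284; B2m 0.35, H2-K1 0.33). Mitochondrial transcripts had a median just below 0, a mean of 0.05 and a test pointing up (8 genes, 0 passing or over the list alone, adjusted p = 0.647; mt-Nd4 0.31, mt-Atp6 0.10). Monocyte markers (3 genes, median 0.14, adjusted p = 0.527) and macrophage markers (5 genes, median -0.11, adjusted p = 0.67) were not called, with 0 genes passing over the list alone.

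The same split of monocyte/macrophage-like barcodes asked whether these genes go with Icam1 in another class. After thinning, 107 of these barcodes had Icam1 (37, 50 and 20 by replicate) and 2957 did not. The chemokine genes Cxcl9 (ENSMUSG00000029417; chromosome 5, 92321347 to 92328079) and Cxcl10, both induced by interferon, rose with it. Cxcl9 rose by 2.65 ± 0.43 (log2, adjusted p = 0.00942), from 50.7 ± 25.3 to 330 ± 250 CPM (SD, n = 3, from 81 and 20 UMIs). Cxcl10 rose by 1.85 ± 0.35 (adjusted p = 0.0332), from 134 ± 63.2 to 481 ± 246. Each rose in 3 of 3 libraries, as the naming rule required. These were the 2 calls among 2208 genes in edgeR, with 123 at an unadjusted p under 0.05, and DESeq2 called 1. Without replicate 1 or without replicate 3 edgeR called 0 genes, with 148 and 264 at an unadjusted p under 0.05, and without replicate 2 it called 2 other genes. There Cxcl10 had an adjusted p = 0.79 and Cxcl9 was too low in counts for a test. With another random draw of the thinning edgeR called 0 genes (123 at an unadjusted p under 0.05), with Cxcl10 at 0.78 (adjusted p = 0.909). Over all alternatives the adjusted p ran from 2.12e-06 to 0.532 for Cxcl9 and from 2.85e-09 to 0.999 for Cxcl10. The median of all genes in this split moved from -0.10 with TMM to 0.05 with library totals.

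With a preset correlation, monocyte markers were called higher in this class (median 0.58, adjusted p = 0.000601, 3 of 3 libraries), as were interferon-stimulated genes (0.30, adjusted p = 0.000143, 2 of 3 libraries) and the NF-kB list (0.38, adjusted p = 0.00448, 3 of 3 libraries), and macrophage markers (-0.20, adjusted p = 0.0294, 2 of 3 libraries) and mitochondrial transcripts (-0.17, adjusted p = 0.0294, 1 of 3 libraries) were called lower. With an estimated correlation none of these 5 passed, at an adjusted p = 0.773 for the monocyte markers and the interferon list and 0.9 for the others. Of the measured members 1 of 10 interferon-stimulated genes rose, and none passed among 6 monocyte markers, 10 NF-kB targets, 12 macrophage markers and 8 mitochondrial genes. When adjusted over the list alone these counts were 1, 2, 2, 0 and 0. The remaining 12 lists had adjusted p of 0.204 to 0.9 with the preset value. The median lay below 0 although the test pointed up for adhesion (-0.08, mean 0.02), NADPH oxidase (-0.10), growth factors (-0.01) and dissociation stress (-0.07). None of the 5 lists was called without replicate 3 (adjusted p = 0.121 to 0.236) or with another random draw of the thinning (adjusted p = 0.269 to 0.885), and without replicate 1 the NF-kB list (adjusted p = 0.409; 1.06e-14 to 0.91 over all alternatives) and the macrophage markers (adjusted p = 0.0862; 0.000175 to 1) were lost. Without thinning the monocyte markers were called lower (-0.14, adjusted p = 0.00309) and the macrophage markers higher (0.13, adjusted p = 0.0406), so no direction can be read for either marker list.

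Whether the changes differed between the classes was tested directly. Mt2 (ENSMUSG00000031762; chromosome 8, 94172664 to 94173568), which encodes a metal-binding protein, was the single gene of 3320 called, with a difference of 3.73 ± 0.72 (log2, neutrophil-like minus monocyte/macrophage-like; adjusted p = 0.000888). In replicate 3, 18 Mt2 UMIs fell in detected neutrophil-like barcodes, against 1 in each of the other libraries. In monocyte/macrophage-like barcodes with Icam1 it had 5, 0 and 0 UMIs. Without replicate 3 the difference was 0.34, and edgeR called 0 genes, with 172 at an unadjusted p under 0.05. In the full set 143 genes had an unadjusted p under 0.05. Saa3 came next at 1.94 (adjusted p = 0.0909), so the higher number of calls in neutrophil-like barcodes is not shown to be a difference between the classes.

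The last question was how Icam1 is spread over the neutrophil-like barcodes. In 6 subclusters found without Icam1 or the adhesion genes, its level was highest in the smaller subcluster 4 (243 barcodes, led by Cxcl10, Ifit3, Ifit3b, Gbp3 and Ifit1), at 201 ± 34.9 CPM (SD, n = 3). It was 136 ± 42.5 in subcluster 2 (1195 barcodes; Retnlg, Lrg1, Wfdc21, Ifitm6 and Hp), 128 ± 3.93 in subcluster 3 (1835; Cxcl3, Ccdc126, F10, Hilpda and Fam71f2) and 140 ± 16 in subcluster 5 (2595; Ltc4s, Ndufa11, Dnajc19 and Mrpl42). Subcluster 1 (175; Pdpn, Plau, Aldh2, H2-Eb1 and Spp1) had 82.1 ± 97.5, and subcluster 6 (124; Hspa1a, Mgarp, Mt1, Gbe1 and Snhg6) the lowest level, 31.1 ± 36.9, from 5 Icam1 UMIs. Each subcluster was tested against the mean of the others with edgeR's quasi-likelihood test, and adjusted p for Icam1 was taken over the 6 subclusters. Icam1 in subcluster 4 was higher by 0.95 ± 0.31 (adjusted p = 0.00675, 3 of 3 libraries). In subcluster 6 it was at -1.87 ± 0.58 (adjusted p = 0.00675, lower in 3 of 3 libraries). Without replicate 1 subcluster 6 was at -1.31 (adjusted p = 0.0656, the highest of a range from 0.000686). Adjusted over all 2857 genes, the values were 0.0267 for subcluster 4, 0.0101 for subcluster 6, 0.000148 for subcluster 2 and 0.0144 for subcluster 3. Subclusters 2 (0.95 ± 0.21, adjusted p = 0.000202; 1.83e-07 to 0.652 over the alternatives) and 3 (0.56 ± 0.20, adjusted p = 0.00979) were also called higher, each above the mean of the others in 2 of 3 libraries in CPM. Subcluster 1 (-0.76 ± 0.48, adjusted p = 0.143) and subcluster 5 (0.15 ± 0.21, adjusted p = 0.469) were not called, but without replicate 1 they were, at -2.83 (adjusted p = 0.000525) and 0.64 (adjusted p = 0.0186); over the alternatives with all 6 subclusters the adjusted p reached 0.697 and 0.962. The order of subclusters 2, 3 and 5 depended on the scaling, since with library totals subcluster 3 was not called (0.26, adjusted p = 0.249; 1.72e-05 to 0.652 over the alternatives) and subcluster 5 was (0.44, adjusted p = 0.0498).

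**Figure D5:**
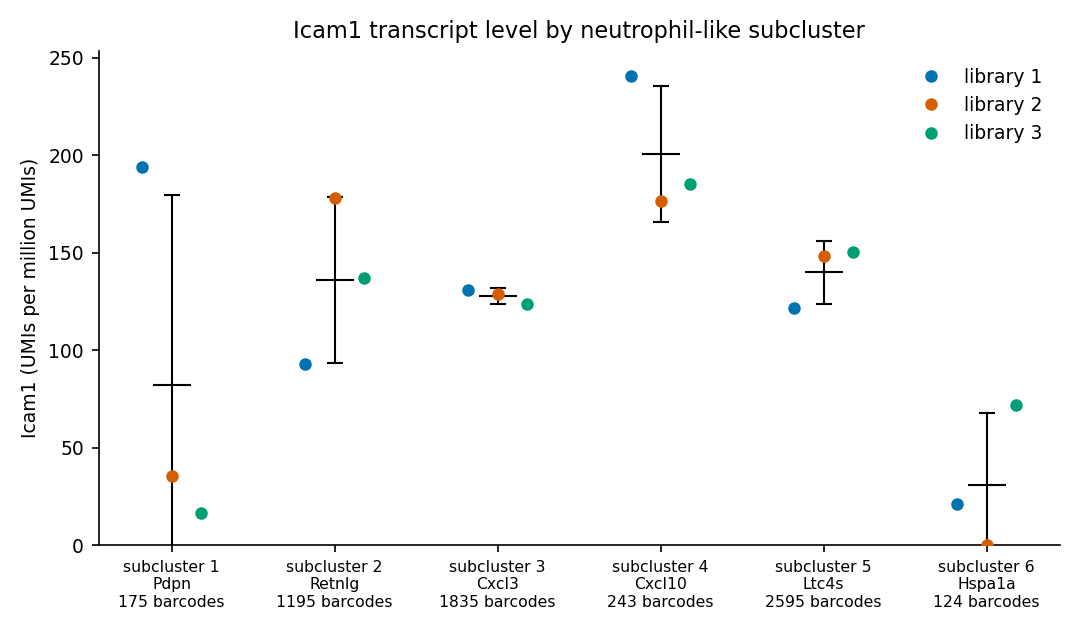
Icam1 level in CPM (vertical axis) in 6 neutrophil-like subclusters for the 3 libraries (points), with the mean and SD (black; the bars of subclusters 1 and 6 are drawn down to 0 only). Subcluster 4 lies highest at 201 and subcluster 6 lowest at 31.1.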

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

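Except for the test on epithelial transcripts, all tests of explanations were chosen after the results were seen. The design gives 1 group, so no biological explanation was tested.

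Mt2 was noted because its change with Icam1 differed between the classes, by 3.73 (log2) between neutrophil-like and monocyte/macrophage-like barcodes. That value rests on 18 UMIs in replicate 3 and was 0.34 without that replicate. Of 10 splits of the sums, the real one included, all 10 gave at least the real 1 call and the highest other gave 6.

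A cluster of 261 barcodes, used in no comparison, was noted because it held the neutrophil genes S100a8 and S100a9 together with the T-cell gene Cd3e. S100a8 was detected in 90.7% and Cd3e in 65.1% of its barcodes, against 17.1% and 74.9% in T-cell-like barcodes. Free neutrophil RNA at the level of other T-cell droplets is argued against, since the S100a8 and S100a9 level was at least 33.3 times the T-cell-like level in each library. Some difference was built in, as the clustering had set these barcodes apart from T-cell-like ones. The median depth was 0.924 of the sum of both classes' medians (0.843, 1.008 and 0.92 by replicate), which goes with droplets that hold a T cell and a neutrophil. S100a8 and S100a9 stood at 24.9%, 19.9% and 19.5% of the neutrophil-like level, which goes with full pairs less well. In replicate 1 the medians were 806.5 UMIs in neutrophil-like and 1207 in T-cell-like barcodes, so a full pair would lie higher than 24.9%. Random pairing at the assumed rate would give 101.4 barcodes, 2.57 times fewer. If these barcodes are pairs, whether they formed in the tumour, in the tube or at a higher rate than assumed cannot be told apart.

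NF-kB targets such as Tnf and Nfkbia were higher in Icam1-detected neutrophil-like barcodes. A split by the detection of any gene is argued against as the cause of this direction. The list was called higher in 0 of 20 control splits. It was not inert there, with medians from -0.52 to 0.03. In most of these splits it was lower at an unadjusted camera p under 0.05 with the preset correlation, down to 4.13e-10 in the split by Ndufb3. A small p-value alone therefore does not set the Icam1 split apart. Another mix of the 6 subclusters is argued against as the whole cause, since the list was called at a median of 0.62 with undetected barcodes drawn to the subcluster mix of detected ones, and in subclusters 3 and 5 alone at 0.47 with subcluster in the block and 0.49 without it. RNA of macrophages is argued against by their markers, whose log2 ratio was -0.029 ± 0.305 (SD, n = 3). RNA of monocytes is argued against by the level of the list's members in monocyte-like barcodes. Against undetected neutrophil-like barcodes they lay there at a median log2 ratio of -1.55 ± 0.249 (SD, n = 3). Each of the 6 called ones was lower in 3 of 3 libraries. Summed monocyte markers were higher in Icam1-detected barcodes in 3 of 3 libraries (2 of 3 in CPM). Their log2 ratio was 0.197 ± 0.2285 (SD, n = 3), below the list median of 0.58. As Icam1 is itself a target of NF-kB, a shared response may underlie the pattern, but with an estimated correlation the list was not called, and free RNA of neutrophils themselves and the state of the cells after sorting stay open.

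The lower level of blood neutrophil genes such as Retnlg and S100a8 is weaker evidence. The list was called lower in 17 of 20 control splits, so any split by detection may give it. With undetected barcodes drawn to the subcluster mix of detected ones it was called at a median of -0.24, and over the 8 members measured in each fit the median was -0.18 against -0.14 before. In subclusters 3 and 5 alone it was not called with subcluster in the block or without it, with medians of -0.14 and -0.10 over these 8. The members differed widely (SD 0.701 with the drawn mix), so another mix of subclusters as the cause cannot be told apart from a change within them.

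The sums were also split in other ways into groups of equal size, with 10 splits per result, the real one included, which is too few to exclude chance. For the neutrophil-like split the real 36 genes stood against at most 3, and against 0 in the 3 others that part every pair. The real 6 lists stood against at most 5, and 3 in those that part every pair. Splits by the detection of control genes called 2 to 16 lists, so the count of 6 lists does not set the Icam1 split apart. For monocyte/macrophage-like barcodes the real 2 genes stood against at most 1, and the real 5 lists against at most 5, in a split that also parts every pair. For adhesion genes between the classes the real 15 stood against 0. In each of these results the other splits mixed both kinds of sums within a group. A real difference then adds to their spread and can lower their calls, so fewer calls there do not argue against chance. Among the 10 splits of the sums, the count of monocyte/macrophage-like lists was reached by 2, the real one included. Each of the other counts was reached by 1 of these splits, the real one. Over 100 assignments of subclusters, the real one included, 4 subclusters with Icam1 called stood against at most 3. These assignments mixed sums of different subclusters within a group and ignored the library, unlike the real grouping. They therefore cannot exclude chance for that count.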

How the results depend on the processing

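The alternatives with the highest doublet scores left out, sums of all UMIs, library totals (TMM for the class difference), library and subcluster as block, subclusters 3 and 5 alone, undetected barcodes with the subcluster mix of detected ones, the largest subclusters and, for lists, resolution 0.5, 2 Icam1 UMIs, another seed and the purity filter were chosen after the data were seen. As a share of UMIs, Icam1 remained higher in neutrophil-like than in monocyte/macrophage-like barcodes in all 12 alternatives (1.38 to 1.68). The 26 genes named from the neutrophil-like split kept their sign in all 541 gene and setting pairs, passing in 359. The cause of these changes was not tested. All settings named before the data were examined were run, and at this depth small changes are missed in every split. With at least 500 genes and at most 5% mitochondrial UMIs the neutrophil-like share was 28.6%, the split calls were 10 (neutrophil-like) and 0 (monocyte/macrophage-like), the class difference 0, the subclusters called 2 and Itgal -0.0564. Without thinning these splits gave 160, 76 and 27 genes and 12 lists, with detected barcodes deeper than undetected ones. Thinned to the 50th percentile the neutrophil-like split gave 54 genes (35 of them lower), and the monocyte/macrophage-like split and the class difference 6 each. At least 2 Icam1 UMIs before thinning against 0, which leaves out barcodes with 1 and made detected barcodes deeper (as in replicate 1 of the monocyte/macrophage-like split, with medians of 5584 and 3875 UMIs), gave 14 and 1, another random seed 23 and 0, sums of all UMIs 69 and 17, no filter on low counts 72 and 105, and the DESeq2 Wald test 16 and 1. Leiden resolution 0.5 gave 4 and the highest doublet scores left out 5 in the monocyte/macrophage-like split. Without the replicate block the splits gave 9 and 0 and the class difference 0, so most calls need the pairing by library. With library and subcluster as block, which kept subclusters 3 and 5 alone, 19 genes were called and the granule list turned to 0.10, and in these subclusters without that block to 0.0394, with 21 genes. With the subcluster mix matched 32 genes were called. Leaving out a replicate gave 5 to 23 genes, 0 to 2, and 0 to 2 for the class difference, which gave 3 with TMM and 2 with DESeq2 size factors. Where edgeR called 0 genes, 80 to 264 had an unadjusted p under 0.05 in the monocyte/macrophage-like split and 133 to 172 in the class difference. With an estimated correlation 0 lists were called by camera. Uncalled integrin differences changed sign, Itgb2 to -0.18 and Itgal to -0.23 with library totals, Itgal to -0.0208 with DESeq2 size factors and -0.0124 with the DESeq2 Wald test. Leaving out a replicate gave -0.0335 to 0.161 for Itgal, -0.122 to 0.0262 for Itgam and -2.83 to 0.23 for Icam1 in subcluster 1. In the 3 largest subclusters alone subcluster 5 was -0.62, and with library totals subcluster 3 was -0.16 and 0 were called.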

Other observations

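The test on epithelial transcripts was written before its result was seen. Other values here were chosen after the data were seen.

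Neutrophil-like barcodes held high levels of chemokine and cytokine transcripts. Cxcl2, which attracts neutrophils, reached 15612 ± 5144 CPM (SD, n = 3), against 1137 ± 364 in monocyte/macrophage-like barcodes, and Il1b reached 13077 ± 2079 against 1496 ± 330. Csf1, a growth factor of macrophages, was 387 ± 8.96 against 24.8 ± 1.54. The receptor genes Csf3r and Cxcr2 stood at 633 ± 146 and 370 ± 84.8.

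T-cell-like barcodes included a cluster with Il17a, Tcrg-C1 and Trdc (6.52% ± 2.81 of barcodes), and over the class Il17a was at 569 ± 222 and Trdc at 386 ± 211 CPM. Epithelial-like barcodes held Lcn2 at 6767 ± 426, Epcam at 665 ± 45.4, Cxcl1 at 78.0 ± 68.3 and Csf3, which drives neutrophil production, at 15.3 ± 9.16 from 40 UMIs.

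As the title speaks of adhesion, it was asked whether Icam1-detected neutrophil-like barcodes carry more epithelial transcripts, which could mark contact with tumour cells. The summed level of epithelial markers was 107 ± 38.1 CPM in detected and 113 ± 21.1 in undetected barcodes (SD, n = 3; 25 and 342 UMIs). The level was lower in detected barcodes in 2 of 3 libraries, the outcome set before as evidence against, but the mean log2 ratio with a prior count of 0.5 was -0.044 ± 0.265, within its spread and above 0 in 2 of 3 libraries (exact sign-flip permutation test, two-sided p = 1; 3 libraries allow no p below 0.25). These counts are too few to decide.

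T-cell receptor variable segments had 56, 164 and 47 UMIs over 163 genes, against 4899, 9615 and 4684 UMIs of constant segments.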
